A study of Mus musculus with 9 samples.

How the data were processed

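Gene expression was measured on 9 dual-colour Agilent mouse arrays, 5 of cells treated with Fzd8-CRD and 4 of control cells. Groups were taken from the treatment label of each array. The treatment protocol field names the Wnt inhibitor for all 9 arrays, the controls included, so what the controls received instead is not given in the sources used here. Replicate numbers were given in accession order and pair no arrays across the groups. Per the labels, RNA of the sorted cells was labelled with Cy5 and a pooled reference RNA with Cy3, so that a positive log ratio means more RNA in the tumour cells than in the reference. The labels disagree on the reference, which one field calls a universal mouse RNA, one a pool of strains and one a universal human RNA, so ratios are not read as levels. Whether the same reference RNA was used on the slides of both groups is not given in the sources used here, and a ratio difference between the groups would carry any difference between references.

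The spot intensity values, linear foreground means and local background medians of each dye, were written by Agilent Feature Extraction 9.5.3.1, per the file headers. The log10 ratio of Cy5 to Cy3 in the same files is the scanner software's own background-corrected and dye-normalized value, per the file headers. The deposited series table holds a linear ratio for each array. Its log2 values correlated at 1 with the scanner's log ratio on every array, which settles scale and direction, and the median linear ratio lay between 0.833 and 0.954. Between 4368 and 9418 probes per array were empty in it, and 0 of them were well above background in Cy5.

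Each array held 45018 spots, of which 1639 were controls. Background was corrected with the normexp method (offset 50) in limma 3.58.1 under R 4.3.3, with version 1.17.8 of the data.table package, and ratios were normalized within each array by loess, with control spots given no weight. Over all arrays 1229 spots marked as outliers were left out, and 0 spots were saturated. Spots of 1 probe were averaged, which gave 41174 probes, and the 26722 probes (64.9%) that were well above background in Cy5 on at least 4 arrays were kept. A gene with several kept probes, as 6094 genes had, was represented by its brightest probe over all arrays, which left 18212 genes. Probes were named through RefSeq or Ensembl accessions (23374 probes), current symbols (6733) or synonyms (2919), and 8148 kept the name in the file. The number of arrays limits the precision.

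Groups were compared with limma's linear model and moderated statistics, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are Fzd8-CRD minus control on the log2 scale, with the standard error (SE) of the fit. Because background correction adds an offset, differences of dim genes are understated. For a gene not well above background on any array of a group, a bound is given as at least N-fold. It compares the mean of the brighter group with the lowest signal well above background, after loess and quantile normalization of mean intensity. The bound is for group means, holds no spread between arrays and is open to dye bias. Each dye was also tested alone after quantile normalization. The 32 gene lists, fixed before the data were examined, were tested with camera (preset correlation 0.01, and with an estimated correlation), with fry, and by a two-sided exact permutation of each list's mean score over the 126 splits of the arrays, where the smallest possible p is 0.00794. Simulated data with the spread of the 18212 genes, each drawn independently of the others, were used to test the gene comparison. Of genes changed by 0.5, 1 and 2 log2 units, 11.9%, 46.3% and 80.3% were recovered, with 3 false calls, and 1 list shifted by -1 was found among 32. Because these genes were not correlated, the simulation does not measure how often lists pass in error. Other splits of the real arrays gave a median of 9 lists past camera.

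Genes to be named were also fixed by rule before the data were examined: the 12 largest rises and 12 largest falls past the threshold with groups that did not overlap, up to 4 members with the smallest p from each list past its test, up to 2 members with the largest difference from each other list, and a fixed set of pathway, transgene and cell type genes. This gave 126 genes, of which the text names a part, and 1 is not reported here. Members of a list named outside this rule, because the list held 5 or fewer changed genes (Twist1, Mmp7, Dkk1, Lrp6, Fzd6, Ror1, Cldn4, Cxcl9, Cd8b1, Egf, Socs3, Gadd45b, Atf4, Trib3, Ankrd37, Higd1a, Bax, Fdft1, Msmo1, Zeb1, Cdh2, Dll4, Maml1, Mfng and Sufu), were chosen after their values were seen. Alternatives covered background correction (a normexp offset of 16, none), the scanner's log ratio, the deposited series table, median centring, scaling and quantile normalization of mean intensity, Cy5 alone, filters on dim probes, the mean of a gene's probes, array weights, trended robust variance, slide or scan day as a random block, other set tests, a minimum size of change, and leaving out each array. Random blocks and trended variance were carried into the list tests through the moderated statistics, and array weights directly. Averaging the closest pairs of arrays and removing probe GC content were added after seeing the data. No genome sequence was used here, and the tumour model behind each array was not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.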

Results

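Tumour cells were taken from MMTV-Wnt-1 and MMTV-Her2 mice, transgenic lines in which a mammary tumour virus promoter drives the Wnt-1 ligand or the receptor tyrosine kinase Her2 in the mammary gland. Freshly isolated cells had been sorted for absence of green fluorescent protein. The comparison asked how expression differs in cells treated with Fzd8-CRD, the soluble Wnt-binding domain of the receptor Frizzled 8, which keeps Wnt proteins from their receptors. The series' design text describes 5 biological replicates with the inhibitor and 4 controls. The labels give both tumour models for every array, so Wnt-1 and Her2 tumours could not be separated.

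Between 52.5% and 60.0% of probes were well above background in Cy5 on the Fzd8-CRD arrays, against 63.8% to 70.8% on the control arrays, and the reference RNA in Cy3 showed the same order (58.7% to 65.7% against 71.8% to 74.9%). All 4 control arrays shared 1 slide and 1 scan day, whereas the 5 Fzd8-CRD arrays lay on 4 other slides scanned on 2 other days, 367 and 378 days later. Slide and treatment are therefore not separable by a direct comparison within a slide. The Cy3 signal of the reference alone differed between the groups for 10748 of 18212 genes (59.0%), with an absolute log2 difference of at least 1 for 228 of them. Whether both groups' slides carried the same reference RNA is not given in the sources used here, and ratio differences would carry any difference between references. Log2 ratios of control replicate 2 correlated across genes at 0.618 to 0.737 with the other 8 arrays, while the other controls correlated with each other at 0.898 to 0.979 and the Fzd8-CRD arrays at 0.892 to 0.976. Control replicate 2 had higher medians of lymphocyte, macrophage, MHC class II and erythrocyte markers than the other controls. Its lymphocyte median stood 1.98 log2 units above the gene means, against -0.37 to -0.032 in the other controls. Its fibroblast (1.22) and endothelial medians (1.46) were also the highest of the 9 arrays. The closest pairs were Fzd8-CRD replicates 1 and 2 (r = 0.976) and control replicates 3 and 4 (r = 0.979). Their Cy5 signals differed by median absolute deviations of 0.246 and 0.162, above those of their Cy3 signals (0.164 and 0.0558). Each array was counted as a replicate.

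**Figure D1:**
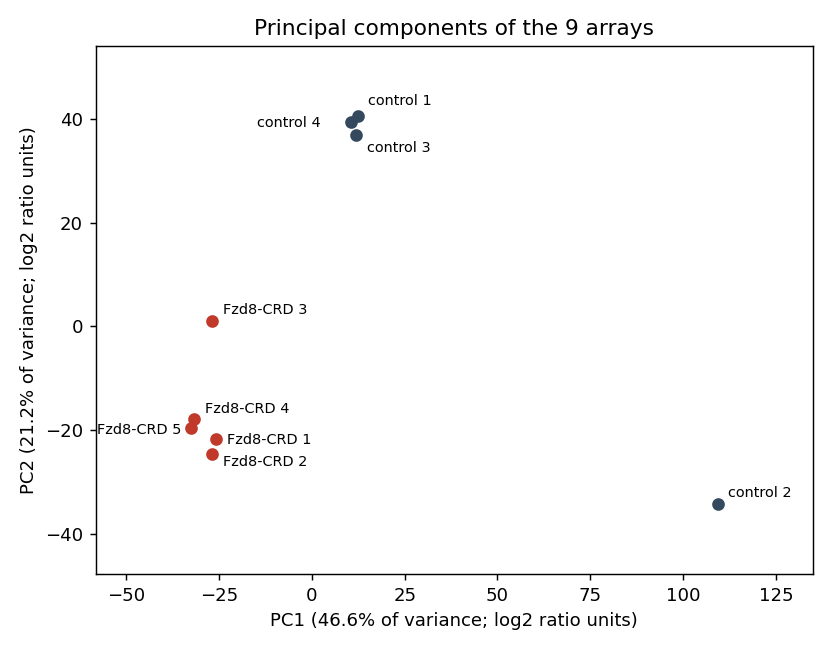
Principal components 1 and 2 of the log2 ratios of 18212 genes, in log2 ratio units, with 1 point per array (red, Fzd8-CRD, n = 5; dark blue, control, n = 4). Component 1 holds 46.6% of the variance and sets control replicate 2 (109.3) apart from the other 8 arrays, and component 2 (21.2%) places the other controls at 36.8 to 40.6, above every Fzd8-CRD array.

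Expression of 2616 of 18212 genes changed between Fzd8-CRD and control arrays, of which 1200 rose and 1416 fell. The largest rises included Col16a1 and Eln, a collagen and the elastic fibre protein elastin, by 2.26 (SE 0.41, adjusted p = 0.0097) and 1.84 log2 units (SE 0.16, adjusted p = 0.00116). Ucma, a secreted cartilage matrix protein, rose by 1.98 (SE 0.20, adjusted p = 0.00174), and the lysosomal protease gene Ctsl by 1.82 (SE 0.16, adjusted p = 0.00116). The globin gene Hbb-bt, at a log2 ratio of 1.12 ± 1.69 (SD, n = 5) against 7.59 ± 2.23 (SD, n = 4), fell by 6.47 (SE 1.12, adjusted p = 0.00863) and was well above background on 3 of 5 Fzd8-CRD arrays. The chemokine gene Ccl4 fell by 4.17 (SE 0.47, adjusted p = 0.00279), and so did Rgs5, a pericyte marker (-2.89, SE 0.42, adjusted p = 0.00539), and the cytokine gene Il6 (-2.47, SE 0.31, adjusted p = 0.00344). Ifnb1, which encodes interferon beta, fell by 3.01 (SE 0.16, adjusted p = 0.000116) and was well above background on 1 of 5 Fzd8-CRD arrays. The Cy3 signal also differed for Hbb-bt (-1.76) and Eln (1.18), in the direction of Cy5 alone (-7.42 and 3.34). For Alas2, another gene that fell, log2 Cy3 stood at 12.81 on control replicate 2, where log2 Cy5 was 17.66. On the other controls of the same slide its Cy3 stood at 6.48 to 6.75. Whether such Cy3 differences lie in the reference RNA was not tested. The other probe of Col16a1 differed by 0.49. An absolute log2 difference of at least 1 was reached by 828 changed genes, 339 higher and 489 lower. The median over all genes was -0.073. The groups did not overlap for 3571 genes (19.6%, against 1.59% by chance). The number changed was 1340 without control replicate 3, 1620 without control replicate 4, 1497 without Fzd8-CRD replicate 1 and 3095 without control replicate 2. The genes higher numbered 790 without Fzd8-CRD replicate 2, while the genes lower numbered 930 and 932 without Fzd8-CRD replicates 4 and 5. With the closest pairs averaged, an alternative chosen after seeing the data, 340 genes changed, all among the 2616. Slide as a random block gave 5505 with a negative consensus correlation of -0.17. Since no slide carried arrays of both groups, the block removes no slide difference between the groups.

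**Figure D2:**
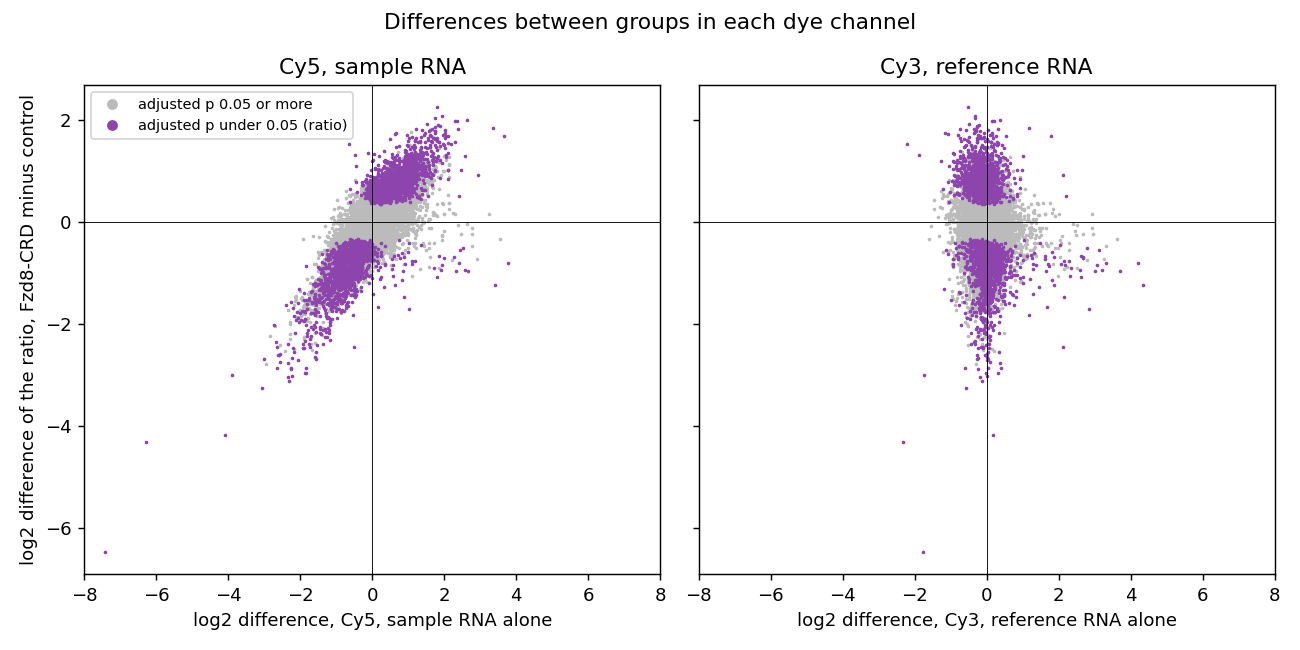
Log2 difference of the ratio (vertical axes, Fzd8-CRD minus control) against the log2 difference of each dye alone (horizontal axes), 1 point per gene for 18212 genes, with the 2616 changed genes in purple. Cy5, the sample RNA, moved the way of the ratio for 94.7% of changed genes, of which 1498 were also called with Cy5 alone, while Cy3, the reference RNA, spreads to either side of 0.

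Genes activated by Wnt/beta-catenin signalling did not pass the test for a shift of the group in a shared direction. The mixed test of fry, for change of members in either direction, passed (adjusted p = 2.56e-06), as it did for 28 of 32 lists. Of 33 measured members, 1 rose and 1 fell, also when adjusted over the list alone, namely the transcription factor gene Twist1 (0.99, SE 0.18, adjusted p = 0.00957) and the protease gene Mmp7 (-0.81, SE 0.11, adjusted p = 0.00436), and the median log2 difference was -0.13 (camera adjusted p = 0.984, and 0.982 with an estimated correlation). Axin2, the feedback inhibitor most widely read as a Wnt target, stood at 0.0079 ± 0.090 (SD, n = 5) against 0.061 ± 0.33 (SD, n = 4), a difference of -0.054 (SE 0.16, adjusted p = 0.837), and was well above background on 3 arrays of each group. Its log2 Cy5 signal was dim on every array (6.42 to 6.97), so a difference of Axin2 would be understated. The stem cell receptor gene Lgr5 differed by -0.22 (SE 0.18, adjusted p = 0.411) and Myc by 0.17 (SE 0.15, adjusted p = 0.455). Differences of the feedback inhibitor gene Nkd1 (-1.26, SE 0.41, adjusted p = 0.0692), Ccnd1, which encodes cyclin D1 (-1.01, SE 0.34, adjusted p = 0.0742), Tnfrsf19 (-1.20, SE 0.40, adjusted p = 0.0758) and the transcription factor gene Lef1 (-0.77, SE 0.27, adjusted p = 0.0845) did not pass the threshold. With Cy5 alone Ccnd1 (-1.30) and Tnfrsf19 (-1.30) did pass. Lef1 was well above background on 2 of 5 Fzd8-CRD arrays, and a second probe of Lef1 and 1 of 3 probes of Myc went the other way. Without control replicate 2 the list median was 0.030 and 4 members fell, Mmp7 (-0.83), Nkd1 (-1.49), Tnfrsf19 (-1.44) and the Wnt inhibitor gene Dkk1 (-0.61), while Twist1 rose. The list median was also above 0 without background correction (0.0042), with the scanner's log ratio (0.36), the deposited series table (0.40), scaling between arrays (0.15), Cy5 alone (0.013) and probes above background on all arrays (0.17).

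The transgene-related genes did not pass the threshold in the chosen processing. Wnt1 stood at 2.32 ± 1.15 (SD, n = 5) against 2.55 ± 0.50 (SD, n = 4), a difference of -0.23 (SE 0.54, adjusted p = 0.793). Erbb2, the gene of Her2, differed by 0.37 (SE 0.14, adjusted p = 0.114), but the gene Erbb2 passed with Cy5 alone (0.77), scaling between arrays (0.65) and array weights (0.49), among other alternatives. Its other probe differed by 0.063. Wnt1 ranged from 1.23 to 3.60 over the Fzd8-CRD arrays. With the scanner's own log ratio, Wnt1 was higher by 2.04 (adjusted p = 0.00585). Over the alternatives tried the adjusted p of the gene Wnt1 ranged from 0.00558 to 0.999. The array does not show whether this signal came from the transgene or the endogenous gene. Of 13 Wnt ligand genes 1 fell, and 0 passed when adjusted over the list alone (median -0.23, camera adjusted p = 0.29). That gene, Wnt2, was not well above background on any Fzd8-CRD array, and its mean was at least 1.86-fold higher in controls (adjusted p = 0.0457). The groups overlapped for Wnt2, with the lowest control at a log2 ratio of 0.081 and the highest Fzd8-CRD array at 0.091. Among 24 receptors and secreted modulators 1 rose and 2 fell, the same numbers as when adjusted over the list alone (median -0.056, camera adjusted p = 0.984). The rise was that of Lrp6, a Wnt co-receptor gene (0.96, SE 0.22, adjusted p = 0.0213), whose other probe differed by 0.032. Without control replicate 2 the median was 0.066 and 4 members fell, with the receptor genes Fzd6 (-0.69) and Ror1 (-1.02) beside Rspo1 and Dkk2. Rspo1, a secreted activator of Wnt signalling, fell by 1.40 (SE 0.35, adjusted p = 0.0286) but did not pass with Cy5 alone (-0.50), and the secreted modulator gene Dkk2 was at least 2.38-fold higher in controls (adjusted p = 0.00377). Of 22 intracellular pathway genes 3 rose, also when adjusted over the list alone (median 0.22, camera adjusted p = 0.0138; adjusted p = 0.705 with an estimated correlation). They were Tle3 by 0.50 (SE 0.10, adjusted p = 0.0147) and Tle2 by 0.99 (SE 0.27, adjusted p = 0.0403), which encode transcriptional corepressors, and Dvl2 by 0.46 (SE 0.12, adjusted p = 0.0328). A second probe of Tle3 went the other way. Leaving out control replicate 2 left 0 Wnt ligand genes and 2 intracellular pathway genes past the threshold. The intracellular list did not pass with Cy5 alone (median 0.31) or array weights (0.19). The beta-catenin gene Ctnnb1 differed by 0.10 (SE 0.13, adjusted p = 0.615).

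**Figure D3:**
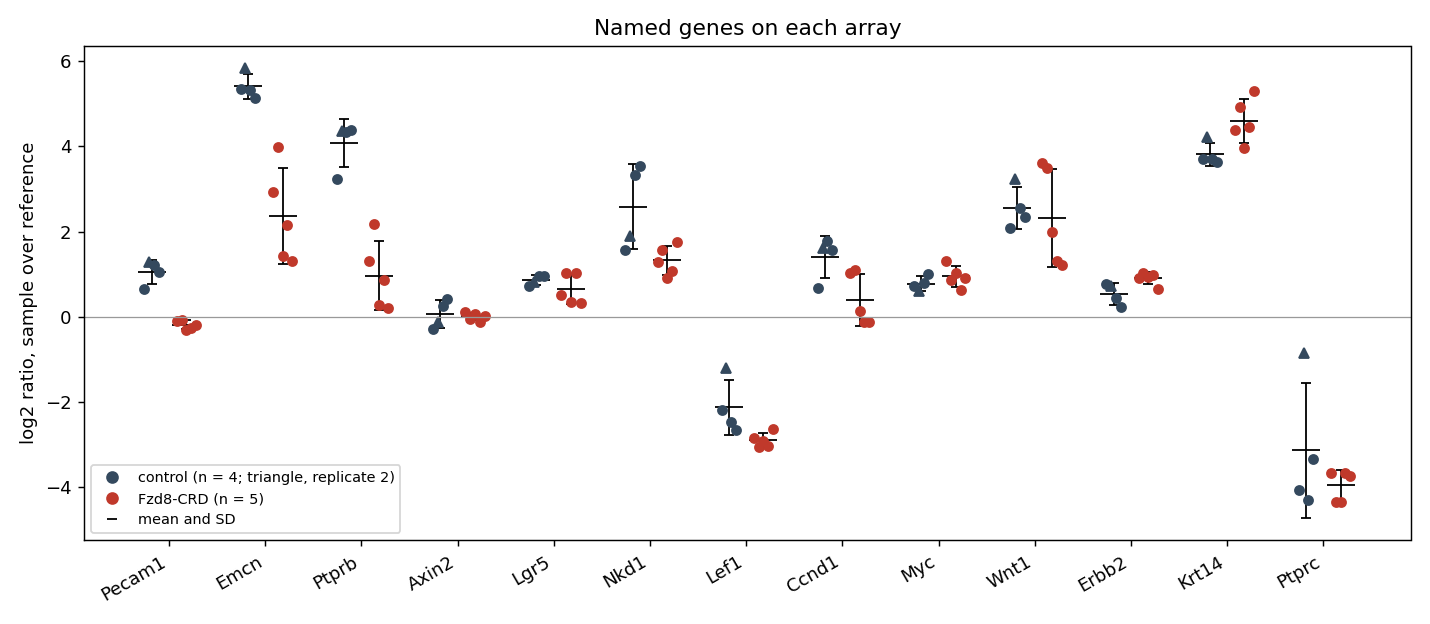
Log2 ratio of sample over reference (vertical axis) of 13 genes on each array, with points for arrays (red, Fzd8-CRD, n = 5; dark blue, control, n = 4; triangle, control replicate 2) and black marks for mean and SD. Pecam1, Emcn and Ptprb lie lower on every Fzd8-CRD array than on every control array, whereas the groups overlap for Axin2 (-0.054), Myc (0.17) and Wnt1 (-0.23).

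Endothelial markers fell together. Of 19 measured members 18 fell, over all genes and adjusted over the list alone, with a median log2 difference of -1.76. Ptprb, a vascular receptor phosphatase, stood at 0.96 ± 0.81 (SD, n = 5) against 4.08 ± 0.57 (SD, n = 4) and fell by 3.12 (SE 0.42, adjusted p = 0.00437). Emcn, which encodes endomucin, fell by 3.04 (SE 0.51, adjusted p = 0.00782), and so did the transcription factor gene Erg (-2.24, SE 0.30, adjusted p = 0.00436), Icam2 (-1.70, SE 0.19, adjusted p = 0.00271) and Sox17 (-1.61, SE 0.21, adjusted p = 0.00424), the last well above background on 4 of 5 Fzd8-CRD arrays. Pecam1, the gene of CD31, was at -0.19 ± 0.10 (SD, n = 5) against 1.05 ± 0.29 (SD, n = 4), with a difference of -1.24 (adjusted p = 0.00306), and was well above background on 2 of 5 Fzd8-CRD arrays. The list passed camera (adjusted p = 3.51e-11; adjusted p = 0.705 with an estimated correlation). The two-sided exact permutation test of its score gave p = 0.0159 (adjusted p = 0.0635). Without control replicate 2 the median was -1.68 and 16 members fell.

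Lists of genes of cell division and of energy and protein production had lower medians in the Fzd8-CRD group. Of 38 DNA replication genes 20 fell, or 23 adjusted over the list alone (median -0.73, camera adjusted p = 7.39e-09; adjusted p = 0.705 with an estimated correlation). Prim1, a primase subunit gene, fell by 1.54 (SE 0.18, adjusted p = 0.00298), and so did Tyms, which encodes thymidylate synthase (-1.46, SE 0.21, adjusted p = 0.00539) and Gins1 (-1.42, SE 0.17, adjusted p = 0.00306). Another of the 3 probes of Tyms differed by -0.11. Of 33 mitosis genes 11 fell, or 17 adjusted over the list alone (median -0.77, camera adjusted p = 6.09e-05; adjusted p = 0.762 with an estimated correlation), among them Prc1 (-1.46, SE 0.28, adjusted p = 0.0114) and Cdk1 (-0.84, SE 0.17, adjusted p = 0.0148). The proliferation marker Mki67 differed by -0.27 (SE 0.41, adjusted p = 0.67). Of 36 oxidative phosphorylation genes 12 fell, or 17 adjusted over the list alone (median -0.44, camera adjusted p = 5.34e-07; adjusted p = 0.705 with an estimated correlation), including Ndufb5 (-1.26, SE 0.21, adjusted p = 0.00784) and Sdhb (-1.11, SE 0.15, adjusted p = 0.00474). Of 43 ribosomal protein genes 10 fell and 1 rose, or 15 and 1 adjusted over the list alone (median -0.32, camera adjusted p = 0.000737; adjusted p = 0.762 with an estimated correlation). Rpsa fell by 1.41 (SE 0.18, adjusted p = 0.00388), with -0.41 on its other probe, whereas Rpl7 rose by 0.55 (SE 0.11, adjusted p = 0.0134) on 1 of 3 probes. The exact permutation test gave the smallest possible p of 0.00794 (adjusted p = 0.0508) for DNA replication, oxidative phosphorylation and ribosomal proteins, and p = 0.0397 for mitosis. Lists of erythrocyte and platelet genes and of the unfolded protein response, which did not pass camera, reached the same smallest p. With control replicate 2 left out, 7 mitosis genes fell (median -0.64). The mitosis medians overlapped between the groups, since control replicate 1 (-0.30, relative to gene means) lay below Fzd8-CRD replicates 1 (0.014), 2 (-0.18) and 3 (-0.25), with the other controls at 0.44 to 0.63. With array weights the ribosomal list did not pass (median -0.20).

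Basal and myoepithelial genes had a higher median in the Fzd8-CRD group and luminal genes a lower one, and the difference between these lists was not tested. Of 24 basal and myoepithelial genes 6 rose and 2 fell, or 13 and 2 adjusted over the list alone (median 0.66, camera adjusted p = 0.000361; adjusted p = 0.718 with an estimated correlation; exact permutation p = 0.0397). Tagln, which encodes the smooth muscle protein transgelin, rose by 1.63 (SE 0.33, adjusted p = 0.0136), the laminin gene Lama3 by 0.90 (SE 0.13, adjusted p = 0.00544) and the basal keratin gene Krt5 by 0.80 (SE 0.13, adjusted p = 0.00712), while Krt6b fell by 1.87 (SE 0.37, adjusted p = 0.0131). The other probes of Lama3 and Tagln differed by 0.0097 and 0.79. Krt5 differed by 0.065 in Cy5 alone and by -0.80 in the Cy3 reference. Krt14 differed by 0.79 (SE 0.26, adjusted p = 0.072), and passed the threshold at 0.92 with control replicate 2 left out. The basal median of Fzd8-CRD replicate 3 (-0.17, relative to gene means) lay below those of control replicates 3 (-0.11) and 4 (-0.089). Of 24 luminal genes 5 fell, also adjusted over the list alone (median -0.56, camera adjusted p = 0.00585; adjusted p = 0.762 with an estimated correlation), led by Prom1 (-1.68, SE 0.26, adjusted p = 0.00575) and Ly6a (-1.22, SE 0.23, adjusted p = 0.0113). The others were Cldn4 (-1.31), Muc1 and Ehf. Prom1 (-0.73) and Muc1 (-0.33) did not pass with Cy5 alone. Krt8 differed by -0.66 (SE 0.36, adjusted p = 0.235). The luminal median turned to 0.19 with the scanner's log ratio, 0.087 with the deposited series table and 0.73 with scaling between arrays, and the list did not pass without background correction (-0.33). Muc1 turned to 0.16 with the scanner's log ratio. Ehf, an epithelial transcription factor gene, fell by 1.42 (SE 0.35, adjusted p = 0.0281) but was higher by 1.67 with the scanner's log ratio (adjusted p = 0.0245). Over the alternatives the adjusted p of the gene Ehf ranged from 0.00449 to 0.294, and it did not pass with control replicate 2 left out (-1.28). Of 14 milk protein genes 1 rose, also adjusted over the list alone (median -0.33, mean -0.15, camera adjusted p = 0.966), namely Mfge8 by 0.95 (SE 0.13, adjusted p = 0.00479).

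**Figure D4:**
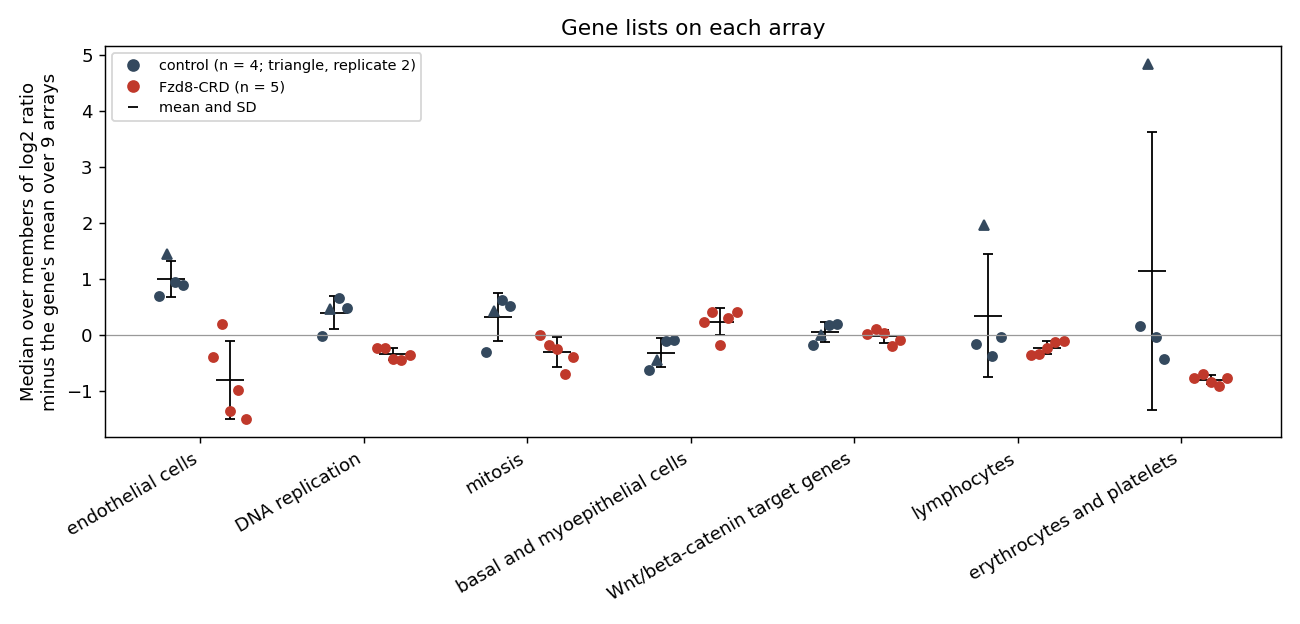
Median over the members of 7 gene lists of the log2 ratio minus each gene's mean over the 9 arrays (vertical axis), with points for arrays (red, Fzd8-CRD, n = 5; dark blue, control, n = 4; triangle, control replicate 2) and black marks for mean and SD. Endothelial genes lie lower on every Fzd8-CRD array than on every control array, Wnt/beta-catenin target genes overlap, and control replicate 2 stands at 1.98 for lymphocytes and 4.85 for erythrocytes and platelets.

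Stromal, immune and inflammatory genes were lower in part, and 4 of these lists passed only with control replicate 2 included. Of 25 fibroblast and matrix genes 4 fell, or 9 adjusted over the list alone (median -0.98, camera adjusted p = 0.0417; adjusted p = 0.844 with an estimated correlation), among them Thy1 (-1.95, SE 0.39, adjusted p = 0.0129, with -0.16 on its other probe) and Vim, the gene of vimentin (-1.17, SE 0.33, adjusted p = 0.0453). Of 23 macrophage genes 2 fell, also adjusted over the list alone (median -0.60, camera adjusted p = 0.00488; adjusted p = 0.762 with an estimated correlation), namely Mrc1 (-0.70, SE 0.19, adjusted p = 0.0376), well above background on 1 of 5 Fzd8-CRD arrays, and Ccr2, which was at least 1.31-fold higher in controls. Of 12 MHC class II genes 2 fell, also adjusted over the list alone (median -0.63, camera adjusted p = 0.0177; adjusted p = 0.762 with an estimated correlation), Cd83 (-2.16, SE 0.39, adjusted p = 0.00959) and H2-Aa (-1.90, SE 0.42, adjusted p = 0.0186), well above background on 4 of 5 Fzd8-CRD arrays. Of 31 interferon response genes 5 fell, or 10 adjusted over the list alone (median -0.58, camera adjusted p = 0.0138; adjusted p = 0.844 with an estimated correlation), the chemokine genes Cxcl10 (-1.94, SE 0.38, adjusted p = 0.0123) and Cxcl9 (-1.01), Usp18 (-0.99), Psmb8 (-1.25) and Oasl1 (-0.90). Of 23 NF-kB and cytokine genes 6 fell, or 8 adjusted over the list alone (median -0.45, camera adjusted p = 0.0138; adjusted p = 0.762 with an estimated correlation), among them Cxcl1 (-1.31, SE 0.32, adjusted p = 0.0264), though with scaling between arrays the median was 0.0080 and Cxcl1 0.066. Without control replicate 2 the fibroblast (median -0.67), macrophage (-0.31), MHC class II (-0.34) and NF-kB lists (-0.36) did not pass, with 1 macrophage gene falling and 3 fibroblast genes falling and 2 rising. Vim (-0.99) and Mrc1 (-0.62) were then past the threshold no longer. Relative to gene means, the fibroblast median of control replicate 1 (-0.80) lay below every Fzd8-CRD array (-0.76 to 0.24). Its interferon response median (-0.45) lay within the Fzd8-CRD range (-0.46 to -0.015). With Cy5 alone, Mrc1 (-0.44), H2-Aa (-1.18), Cxcl9 (-0.43), Cd8b1 (0.50), Alas2 (-3.91) and Ccr2 did not pass. Interferon genes did not pass without control replicate 3 (-0.46), nor did fibroblasts without that array (-0.90) or without Fzd8-CRD replicate 2 (-0.94), 3 (-0.90) or 4 (-0.92), nor NF-kB genes without Fzd8-CRD replicate 2 (-0.35). Lists of 14 neutrophil genes (0 changed, median -0.54, adjusted p = 0.129), 20 lymphocyte genes (1 rose, Cd8b1 by 1.00 with -1.65 on its other probe, median -0.56, adjusted p = 0.15) and 5 erythrocyte and platelet genes (2 fell, Hba-a1 and Alas2, median -1.71, adjusted p = 0.082) did not pass, with the same numbers adjusted over the list alone. The globin gene Hbb-bt, named Hbb-b1 in the file, was measured but not matched to the erythrocyte and platelet list. Its difference of -6.47 is therefore not counted among these falls, nor in that list's tests. Ptprc, the pan-leukocyte gene of CD45, differed by -0.81 (SE 0.62, adjusted p = 0.381). When control replicate 2 was left out, Ptprc differed by -0.050, the lymphocyte median was -0.13 with 1 gene falling, and the neutrophil median was -0.33 with 1 gene rising. The erythrocyte and platelet list then passed camera at a median of -0.23 with the same number of falls (adjusted p = 0.873 with an estimated correlation).

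Over the 32 lists together, 11 passed camera as lower and 2 as higher. With an estimated correlation 0 passed in camera (smallest adjusted p = 0.705), fry called 8 for a shared direction and 28 for change in either direction, and the exact permutation test gave p under 0.05 for 14 lists and for 0 after adjustment. Of 100 splits of the arrays, the real one included, a camera p as small was reached in 5 for endothelial cells, 6 each for DNA replication and oxidative phosphorylation, 8 for the Wnt intracellular pathway, 12 for basal cells, 16 for ribosomal proteins and 20 for mitosis. The number was 30 for NF-kB, 33 for MHC class II, 37 for macrophages, 40 for luminal epithelium, 42 for interferon response and 49 for fibroblasts. Other splits of the same arrays gave 2 to 16 lists past camera, so the number of lists does not stand apart from that of other groupings. Some of these splits kept most arrays of each group together and so held part of the real difference. The highest number, 16, came from a mixed split, with Fzd8-CRD replicates 2, 4 and 5 beside control replicates 1 and 4.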

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

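The tests of the 2 dyes, of slide and scan day, of probe GC content, of other host cell types and of control replicate 2 were chosen only after the result was seen, whereas that of other splits of the arrays was not.

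In 31 of 324 groups of 4 or 5 arrays, 1 array lay far from the rest for a gene, a gene list or an array measure, and chance marks about 1 group in 20. Control replicate 2 was the outlying array in 13 of them. Its list medians, relative to gene means, were 1.26 for macrophages, 1.98 for lymphocytes, 1.68 for MHC class II and 4.85 for erythrocytes and platelets. Its log2 ratios were 3.90 for Ccl4, 4.64 for Cd83, 4.36 for Foxf1, 10.91 for Hbb-bt, 4.22 for Krt14, 3.16 for Lama3, 5.00 for Nkg7, -0.33 for Vcam1 and 4.22 for Wap. Control replicate 1 lay apart for the cholesterol and fatty acid synthesis list (-0.080), Ptprb (3.23) and Sdhb (-0.91). Control replicate 4 lay apart for Hspb8 (3.28) and for its share of probes above background in Cy3 (74.9%). Among Fzd8-CRD arrays, replicate 1 lay apart for Hba-a1 (1.58), Hbb-bt (4.06), Il6 (2.84) and Mrc1 (0.34), and replicate 2 for Itgam (0.21), Krt5 (4.86) and Cy3 probes above background (65.7%). Replicate 3 lay apart for Sned1 (0.21), replicate 4 for Lama3 (4.56), and replicate 5 for Ctnnb1 (0.64), Klf6 (2.04), Muc1 (0.61) and Wnt5b (3.11).

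Control replicate 2 differed from every other array. A failed hybridisation of the whole array is argued against by its Cy3 reference signal, which correlated with that of the other controls at 0.997 at the lowest. The other controls correlated with each other in Cy3 at 0.9991 to 0.9993. Its Cy5 signal correlated with that of the other controls at 0.906 to 0.912. Cy3 cannot show a fault of the Cy5 labelling or of the sample RNA, which was not tested. Blood and immune cells of the host are a candidate source, since lymphocyte, neutrophil and erythrocyte lists all exceeded those of the other 8 arrays, the smallest excess over the median of the other controls being 2.01 log2 units. The fibroblast (1.22) and endothelial medians (1.46) of control replicate 2, relative to gene means, exceeded those of the other arrays as well. Cells had been sorted for absence of green fluorescent protein, which cells carried it is not given in the sources used here, and whether the sort differed was not tested. The design names tumours of MMTV-Wnt-1 and MMTV-Her2 mice, and a difference in tumour model or tumour stays open, as untested.

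The count of changed genes was 2616, against at most 239 in the other splits drawn from the 9 arrays, and 1 of 100 splits, the real one, gave as many. The same held for higher genes (1200, at most 95 in others, 1 of 100) and lower genes (1416, at most 144, 1 of 100). A random split of the arrays therefore seldom gives such counts, provided that the arrays are independent. With the closest pairs averaged, 340 of the 2616 genes kept their call. A difference in the reference channel as the whole cause is argued against by Cy5 alone for the 1498 of the 2616 that it also called. Cy5 moved the way of the ratio for 94.7% of changed genes (94.65%). Because these genes were picked on a ratio that holds Cy5, that agreement is partly built in. Slide and scan day cannot be told apart from treatment, because every control lay on 1 slide and the reference signal itself differed for 59.0% of genes (59.02%), and the real split is also the split between slides. The effect of Fzd8-CRD therefore stays open beside that of the slides and of the reference RNA on them, in part, as it is not given whether both groups had the same one.

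Endothelial markers were lower on every Fzd8-CRD array. The reference channel is argued against by its median difference of -0.14, since less reference signal would raise the ratio rather than lower it, and probe GC content by a median of -1.66 once it was removed. Control replicate 2 does not account for it, since the median without it was -1.68. Without that array, the 15 endothelial members above background on all arrays lay -1.45 below 67 such members of 7 other host lists (95% interval -2.03 to -1.17 by resampling of genes, which are not independent). All 19 measured members lay -1.46 below 110 (-1.83 to -1.05). Against 5 measured erythrocyte genes alone, which leave out Hbb-bt, the interval was -1.87 to 1.81. Host markers thus did not all fall alike on these arrays. However, this test was chosen after the result was seen, and the endothelial list had the smallest camera p of the 32 lists. A larger fall than in other lists was therefore partly built in, and the resampling holds no spread between arrays. A loss of all host cells alike is not excluded. Chance is not excluded for this list, since 5 of 100 splits gave a camera p as small as 1.10e-12 (smallest of the others 7.80e-19), and fewer endothelial cells among the sorted cells, a treatment effect and the slides stay open, as untested.

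The number of lists past camera (13) was reached or exceeded in 15 of 100 splits, with a highest of 16, so chance is not excluded for it. The camera p of the Wnt/beta-catenin target list (0.96) was reached or undercut in 95 of 100 splits, with a smallest of 0.0207.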

How the results depend on the processing

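Averaging the closest pairs of arrays and removing probe GC content were tests chosen only after the result was seen. No paired analysis was possible because replicate numbers were given in accession order and pair no arrays. Where a cause is not named below, the cause was not tested. Against 2616 genes changed, split into 1200 genes higher and 1416 genes lower, median centring in place of loess gave 614 (309 and 305), averaging the closest pairs 340 (126 and 214), with fewer samples, and a minimum absolute log2 difference of 1 gave 828 by construction. More were called with array weights (6921, 3102 and 3819), slide as a random block (5505, 2468 and 3037) and scan day as a random block (5671, 2499 and 3172), whose consensus correlations were negative (-0.17 and -0.12), and Cy5 alone called 1846 higher. No slide or scan day held arrays of both groups, so these blocks cannot remove a slide or day difference between the groups. Leaving out 1 array gave 1340 to 3095 changed, 624 to 1344 higher and 716 to 1751 lower genes, a Wnt target median of -0.17 to 0.030 and 10 to 14 lists. Lists past camera numbered 20 with scaling between arrays, 8 with array weights and 0 with an estimated correlation. Higher genes made up 45.9% of calls, against 56.1% with the scanner's log ratio and 57.9% with the deposited series table, which moved the median of all genes by 0.10. Quantile normalization of mean intensity left every ratio as it was by construction. The endothelial list kept its direction and call under every alternative that changed the values (-2.05 to -1.15), as did DNA replication (-1.34 to -0.61), mitosis (-1.67 to -0.60), oxidative phosphorylation (-0.75 to -0.39) and basal genes (0.38 to 2.20). Signal over background was lower on the Fzd8-CRD arrays, which limits dim genes.

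The direction turned as follows, in log2 units. Called results that turned were, with the scanner's log ratio, luminal genes 0.19, Cxcl2 0.71, Ehf 1.67, Muc1 0.16, Myl1 -0.71 and Serpinb11 0.50. With the deposited series table they were luminal genes 0.087, Cxcl2 0.71, Ehf 1.67, Myl1 -0.71 and Serpinb11 0.50. With scaling they were luminal genes 0.73, NF-kB genes 0.0080, Cxcl1 0.066, Cxcl2 0.0080, Klf6 0.078 and Myl1 -0.12, and with Cy5 alone Myl1 -0.074. The rest had not passed the threshold. Without background correction they were Wnt targets 0.0042, Wnt receptors 0.047, milk proteins 0.099, Notch 0.10, Axin2 0.0060, Fzd8 0.090 and Wnt1 0.26. With the scanner's log ratio they were Wnt targets 0.36, Wnt receptors 0.25, milk proteins 0.78, unfolded protein response 0.0079, p53 targets 0.076, epithelial-mesenchymal transition 0.066, Notch 0.30, ErbB 0.25, Axin2 0.36, Epgn 0.39, Fzd8 0.24, Lgr5 0.70, Wnt1 2.04 and Wnt5b 0.13. The series table gave Wnt targets 0.40, Wnt receptors 0.25, milk proteins 0.82, neutrophils 0.34, ErbB 0.10 and otherwise the scanner's values. Median centring gave Wnt receptors 0.049, skeletal muscle 0.018, unfolded protein response 0.050, p53 targets 0.13 and ErbB 0.049. Scaling gave Wnt targets 0.15, Wnt receptors 0.13, milk proteins 1.65, Notch 0.093, ErbB 0.59, Epgn 0.081, Fzd8 0.10, Krt8 0.71, Lgr5 0.024, Tnfrsf19 0.15, Wnt1 0.64 and Wnt5b 1.07. Cy5 alone gave Wnt targets 0.013, Wnt receptors 0.097, milk proteins 0.26, adipocytes 0.054, p53 targets 0.13, epithelial-mesenchymal transition 0.0025, Notch 0.046, ErbB 0.27, Axin2 0.074, Ctnnb1 -0.25, Fzd8 0.26, Lgr5 0.26 and Wnt1 0.11. Probes above background on all arrays gave Wnt targets 0.17, Wnt receptors 0.082 and Notch 0.050, and the mean of probes gave ErbB 0.016 and the gene Myc -0.048. Array weights gave Ctnnb1 -0.015, Ptprc 0.12, the gene Tcf7 -0.046 and Wnt1 0.13. Averaged pairs gave p53 targets 0.012, ErbB 0.027 and Axin2 0.033, and removal of GC content gave Wnt receptors 0.023, skeletal muscle 0.031, ErbB 0.0095, Ctnnb1 -0.040 and Fzd8 0.0093. Leaving out 1 array at a time gave ranges that crossed 0 for Wnt receptors (-0.071 to 0.066), milk proteins (-0.40 to 0.033), skeletal muscle (-0.12 to 0.041), hypoxia (-0.17 to 0.057), p53 targets (-0.12 to 0.044), epithelial-mesenchymal transition (-0.28 to 0.068), the list ErbB receptors and ligands (-0.091 to 0.011), Axin2 (-0.17 to 0.065), Ctnnb1 (-0.0039 to 0.17), Fzd8 (-0.17 to 0.0043) and Wnt1 (-0.55 to 0.043). Over all alternatives, genes that had passed gave the same direction and call 1986 times, lost the call 299 times and turned 14 times, and for lists these numbers were 312, 22 and 4.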

Other observations

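Several lists not described so far held single genes that changed. Among 20 unfolded protein response genes 1 rose (Trib3, 0.54) and 3 fell (Atf4, -0.80, Chac1 and Asns), also adjusted over the list alone (median -0.061, camera adjusted p = 0.807), and Chac1, a glutathione-degrading enzyme gene, fell by 2.54 (SE 0.49, adjusted p = 0.0123), as did Asns, which encodes asparagine synthetase (-0.96, SE 0.21, adjusted p = 0.0191). Of 26 p53 and apoptosis genes 3 fell, or 4 with 1 rise adjusted over the list alone (median -0.035, camera adjusted p = 0.984), namely Bax (-0.81), Gdf15 (-1.25) and Pmaip1 (-1.62, SE 0.28, adjusted p = 0.00908). Of 26 cholesterol and fatty acid synthesis genes 4 fell, or 9 with 2 rises adjusted over the list alone (median -0.24, camera adjusted p = 0.179), among them Fdft1 (-0.66), Msmo1 (-0.90) and Fdps (-1.06, SE 0.19, adjusted p = 0.00924), for which 1 of 2 probes went this way. Of 14 heat shock genes 1 fell, also adjusted over the list alone (median -0.29, camera adjusted p = 0.28), namely Hspb8 (-1.60, SE 0.25, adjusted p = 0.00629). Of 26 immediate early and dissociation genes 2 rose and 1 fell, also adjusted over the list alone (median 0.17, camera adjusted p = 0.129), the rises being Socs3 (1.17) and Gadd45b (0.75) and the fall Klf6 (-1.33, SE 0.25, adjusted p = 0.011), which turned to 0.078 with scaling between arrays.

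In the epithelial-mesenchymal transition list of 24 genes 1 rose and 2 fell, or 1 and 4 adjusted over the list alone (median -0.13, camera adjusted p = 0.807), with a rise of Cdh2 (1.36) and falls of Zeb1 (-1.03) and the epithelial splicing factor gene Esrp1 (-1.58, SE 0.28, adjusted p = 0.0092). This list mixes mesenchymal genes with epithelial ones such as Esrp1, so a test for a shared direction cannot show or exclude a transition. Of 21 Notch genes 1 rose and 3 fell, or 2 and 3 adjusted over the list alone (median -0.050, camera adjusted p = 0.935), namely Maml1 (0.63), Dll4 (-1.23), Mfng (-0.85) and Notch4 (-1.29, SE 0.30, adjusted p = 0.0207). Of 11 Hedgehog genes 2 rose, or 2 with 1 fall adjusted over the list alone (median 0.083, camera adjusted p = 0.396), namely Sufu (0.92) and Gas1 by 1.65 (SE 0.38, adjusted p = 0.0209). Of 17 ErbB genes 1 rose (Egf, 0.45), also adjusted over the list alone (median -0.051, mean 0.016, camera adjusted p = 0.807). Of 11 adipocyte genes 1 fell, also adjusted over the list alone (median -0.33, camera adjusted p = 0.289), namely Fabp4 (-1.32, SE 0.28, adjusted p = 0.017). Of 12 skeletal muscle genes 2 rose, also adjusted over the list alone (median -0.064, mean 0.019, camera adjusted p = 0.935), namely Acta1 by 1.30 (SE 0.31, adjusted p = 0.0242) and Myl1 by 0.69, which was well above background on 1 of 5 Fzd8-CRD arrays and turned to -0.074 with Cy5 alone, -0.71 with the scanner's log ratio and -0.12 with scaling. Of 28 hypoxia and glycolysis genes 2 fell (Ankrd37, -0.69, and Higd1a, -0.43), or 0 adjusted over the list alone (median -0.057, camera adjusted p = 0.886). Once control replicate 2 was left out, 3 ErbB genes and 2 adipocyte genes fell, 3 epithelial-mesenchymal transition genes fell and 0 rose, 0 unfolded protein response genes rose, 3 immediate early genes rose, 2 p53 genes fell and 2 cholesterol and fatty acid synthesis genes rose. With Cy5 alone Trib3 turned (-0.32), and Atf4 (-0.54), Bax (-0.65), Gdf15 (-1.23), Pmaip1 (-0.72), Cdh2 (1.08), Sufu (0.67), Egf (0.052) and Fabp4 (-0.59) did not pass. The Cy3 reference differed by 0.76 for Pmaip1 and 0.45 for Fabp4. Other probes of these genes differed by -0.56 for Trib3, 0.11 for Fdft1, 0.16 for Gadd45b, 0.058 for Sufu and, for 1 of 3 probes, -0.35 for Fabp4.

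A gain or loss of a whole chromosome was tested as a hypothesis. Over 180 combinations of array and chromosome the largest shift of a chromosome's median was -0.076 log2 units, and 0 exceeded 0.2 together with all 1000 random gene sets of the same size. Positions were known for 18053 genes. Each gene was first centred on its mean over the 9 arrays, which removes a change shared by all arrays and shrinks one shared by most. A change of this size in most cells of a single sample was therefore not seen. One shared across the arrays could not be tested in this way, and one in a small share of cells was not tested.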
